A study of Mus musculus with 8 samples.

How the data were processed

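RNA from a murine oviductal epithelial (MOE) cell line of FVB background was measured by RNA sequencing in 8 libraries, 4 from cells plated on 2D collagen and 4 from cells plated on 3D collagen gels, all kept for 6 h in medium without EGF. Per the labels' protocols, RNA was isolated with TRIzol, purified on Qiagen columns and made into Illumina libraries. Per the submitters' processing notes, reads were counted with HTSeq 0.6.1p1 on the mm10 build and DESeq2 was used. The aligner, the gene annotation, the strand setting and any filter are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

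The deposited values are a normalized signal per gene for 23337 gene symbols. In every library 100% of the values came out as whole multiples of the worth of 1 read, within a tolerance of 0.001 reads. The divisors matched median-of-ratios size factors, the DESeq2 type, recomputed over these 8 libraries, with a largest difference of 3.4e-09. The values are therefore read counts divided by 1 size factor per library, and they are called normalized counts in the text. The recovered depth ranged from 15692699 to 25862036 reads per library, and 14064 to 14598 genes had at least 1 read. This depth resolves abundant genes well and leaves genes with a few reads per library imprecise.

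The test planned before the data were examined assumed raw counts (edgeR's quasi-likelihood test). Because the deposited values are normalized, the main test was limma (version 3.58.1, R 4.3.3) on log2(normalized count + 1), with a trended and robust prior variance, over genes with a normalized count of at least 10 in at least 4 libraries. Fold changes are on this scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. The 2 groups were compared without covariates. edgeR (version 4.0.16) and DESeq2 (version 1.42.0) were run on the recovered reads as alternatives. edgeR's planned test called 680 genes.

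A set of 44 gene lists was fixed before the data were examined, of which 41 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 on the same log2 values (planned on TMM-scaled values, which became an alternative), with p-values adjusted over the lists. The alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way without comparing them with other genes. The genes named in the text were set by a rule fixed at the same time. It took the 12 largest increases and the 12 largest decreases among genes past the threshold with at least 5 CPM in the higher group and no overlap between the groups, leaving out gene models without a descriptive symbol. It also took up to 4 members with the smallest adjusted p of each called list and of the integrin, collagen, matrix protease and YAP and TAZ lists (the 2 most abundant members where fewer than 2 passed), and a fixed set of collagen receptors, collagens, Mmp14, Ctgf, Cyr61, Wnt4, Pax8, Krt8, Cdh1 and Vim. Some genes and lists that the rule took are not reported here. The 5 short lists of LXR targets, aryl hydrocarbon receptor targets, cornified-envelope genes, liver transcripts and intestine transcripts were written after the data were seen.

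Gene positions, exon overlaps and transcript GC content came from GENCODE release M21 on GRCm38, the mm10 build. A current symbol was found for 22877 of the gene symbols, 1916 of them through an older symbol. The GC content of 11709 tested genes was that of the longest transcript. To remove GC trends, a lowess curve (span 30%) of the gene-centred log2 values against GC content was subtracted in each library. Since the strand setting is not given, reads of genes with overlapping antisense partners cannot be told apart. Overlaps that cover at least 8.58% of a named gene's exonic bases are stated with the gene. Smaller overlaps with antisense gene models were found for Wnt7b (6.61%), Pax8 (6.06%), Maf (5.34%), Krt8 (5.16%) and Ddr1 (4.52%). Those of Tln1, Adamts4, Lss, Thbs1, Npr3, Fbxo32, Fn1, Dlk2, Irf7, Adam8, Ddr2 and Bcl6 covered at most 3.67%, and gene models on the same strand covered 3.68% of Itga1 and 1.44% of Col3a1.

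The alternatives set beforehand were other scalings, other filters on low genes, DESeq2, a test against a 1.5-fold change, the replicate number as a block and leaving out each library. Added after the data were seen were edgeR with TMM on the recovered reads (the test planned for raw counts), edgeR with the replicate block, the limma fits with TMM factors or library size, other pseudocounts, the GC correction, leaving out both libraries numbered 4, and leaving out 2D replicate 2 with the GC correction. The computations were tested on simulated data with 200 changed genes. Of the genes changed 2-fold limma recovered 19.4%, and of those changed 4-fold it recovered 77%, with 7.69% of calls false (11718 genes tested). With simulated GC trends the shares were 6.06% and 54% (11725 genes), and after the GC correction 20.6% and 82.7%, with 9.01% of calls false (11617 genes). DESeq2 had 17.0% of its calls false without and 27.1% with the simulated GC trends (11825 genes). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.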

Results

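Gene expression was measured by RNA sequencing in murine oviductal epithelial (MOE) cells, a cell line from the mouse organ that corresponds to the human fallopian tube. The cells were collected at confluence, plated on 2D collagen or on 3D collagen gels and harvested after 6 h in medium without EGF. Each substrate was represented by 4 libraries. Depth ranged from 15692699 reads in 2D replicate 4 to 25862036 in 2D replicate 3, and 14064 to 14598 genes were detected per library. The comparison asks which transcripts differ in these cells between collagen in 2D and in 3D form. It belongs to a study of how cancer derived from the fallopian tube colonizes the ovary.

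Cells on 3D collagen had far less mRNA for the matricellular proteins Cyr61 and Ctgf and for the kinase Nuak2. They had more mRNA for the cholesterol exporter Abca1, the transcription factor Maf and the xenobiotic-metabolising enzyme Cyp1a1. Of the genes of cholesterol synthesis 16 of 24 fell, as did 8 of 26 targets of SRF and MRTF and 7 of 30 focal adhesion components, while 5 of 28 targets of NRF2 rose. Flna and Zyx (Zyx named after its value was seen) count among the lower genes of both the SRF and MRTF and the focal adhesion lists. Of 11820 genes tested with limma, 275 were higher and 401 lower on 3D collagen at an adjusted p under 0.05, so 59.3% of the changed genes were lower. The change was at least 2-fold for 191 of the higher and 224 of the lower genes, and at least 4-fold for 33 and 34. The groups did not overlap for 2177 genes, 18.4% of those tested, where chance gives 2.86%. With library size as the only scaling, which moved the median of all genes by 0.17 (log2), 498 genes were higher and 318 lower (39.0% lower). On the recovered reads edgeR gave 481 and 324 with library size (40.2% lower) and 415 and 380 with upper-quartile scaling (47.8% lower). The counts fell without any single library, which also leaves fewer libraries to test. Higher and lower genes numbered 221 and 370 without 2D replicate 1 and 267 and 350 without 2D replicate 2. They numbered 180 and 213 without 2D replicate 3 and 158 and 313 without 2D replicate 4. Without 3D replicate 1 they were 58 and 133, and without 3D replicate 2 they were 44 and 143. Without 3D replicate 3 they were 44 and 104, and without 3D replicate 4 they were 187 and 239.

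Among the 12 largest decreases, Cyr61 (chromosome 3, 145646976 to 145649981, mm10) fell from 20916 ± 9467 to 1308 ± 556 normalized counts (mean ± SD, n = 4 per group), with a 95% interval of the log2 fold change from −4.84 to −3.16 (limma adjusted p = 0.00144). Ctgf (chromosome 10, 24595442 to 24598683) fell from 31856 ± 12948 to 4745 ± 1919, with a log2 fold change of −2.76 (SE 0.45, limma adjusted p = 0.0127), and 3D replicate 4 stood apart at 1884. An antisense gene model, Gm15270, overlaps 23.2% of the exonic bases of Ctgf. The kinase Nuak2 (chromosome 1, 132316126 to 132333488) fell from 4809 ± 1553 to 505 ± 63.0. Nppb, which encodes a natriuretic peptide, had the largest log2 fold change of the 12, −5.87 (SE 0.82, limma adjusted p = 0.00661), from 152 ± 116 to 1.12 ± 1.33. Npr3, a clearance receptor for natriuretic peptides, had a log2 fold change of −2.90. The log2 fold changes of the secreted ligands Wnt7a and Fgf18 were −3.73 and −3.33, and that of the transcription factor Sox8 was −3.32. Those of the small GTPase Rasl11b and the membrane protein Dlk2 were −2.77 and −2.71. In 3D libraries Rasl11b was highest in replicate 3 (741) and Dlk2 in replicate 4 (92.4), and an antisense gene model overlaps 10.6% of the exonic bases of Sox8. The call of Dlk2 (limma adjusted p = 0.0397) was lost without 2D replicate 2, 3 or 4 or 3D replicate 1, 2 or 3, at limma adjusted p from 0.0592 to 0.125.

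The 12 largest increases began with Maf (chromosome 8, 115682942 to 115707794), which rose from 13.1 ± 9.07 to 130 ± 45.0 normalized counts (log2 fold change 3.42, SE 0.51, limma adjusted p = 0.00822). Cyp1a1 ranged from 2.92 to 19.1 in the 2D libraries and from 38.2 to 172 in the 3D libraries, a log2 fold change of 3.30 (SE 0.66, limma adjusted p = 0.0242). Within groups it was highest in 2D replicate 2 and 3D replicates 1 and 2, the libraries with the highest sums over 8 intestine genes (27.1, 15.9 and 11.2 CPM). In 3D replicates 3 and 4 these sums were 0.472 and 0.597 CPM, under those of every 2D library, and Cyp1a1 still exceeded every 2D value. Abca1 (chromosome 4, 53030787 to 53159895) rose from 148 ± 106 to 922 ± 225, a log2 fold change of 2.91 (SE 0.50, limma adjusted p = 0.0157). Involucrin (Ivl), a structural protein of stratified epithelia, rose from 142 ± 22.7 to 851 ± 311. The log2 fold changes of Neurl1b and Neurl3, of the neuralized family, were 3.15 and 2.58. Those of the protein tyrosine phosphatase Ptprr, of Rhov and of the signalling adaptor Traf1 were 2.75, 2.62 and 2.40. Those of the scaffold protein Grasp and the membrane protein Flrt3 were 2.31 and 2.30. Grasp was lowest among the 3D libraries in replicate 4 (409), and an antisense gene model overlaps part of the exons of Ptprr. In limma, calls were lost without 2D replicate 3 (Cyp1a1, adjusted p = 0.0588; Flrt3, 0.0844; Traf1, 0.0790; Neurl3, 0.0522), 2D replicate 1 (Traf1, 0.0688) and 3D replicate 4 (Flrt3, 0.0787). They were also lost without 3D replicate 1, 2 or 3 for Abca1, Neurl3, Traf1 and Flrt3 (limma adjusted p from 0.0509 to 0.117), without 3D replicate 2 or 3 for Rhov (0.0607 and 0.0630) and without 3D replicate 1 or 2 for Cyp1a1 (0.0762 and 0.0772).

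**Figure D1:**
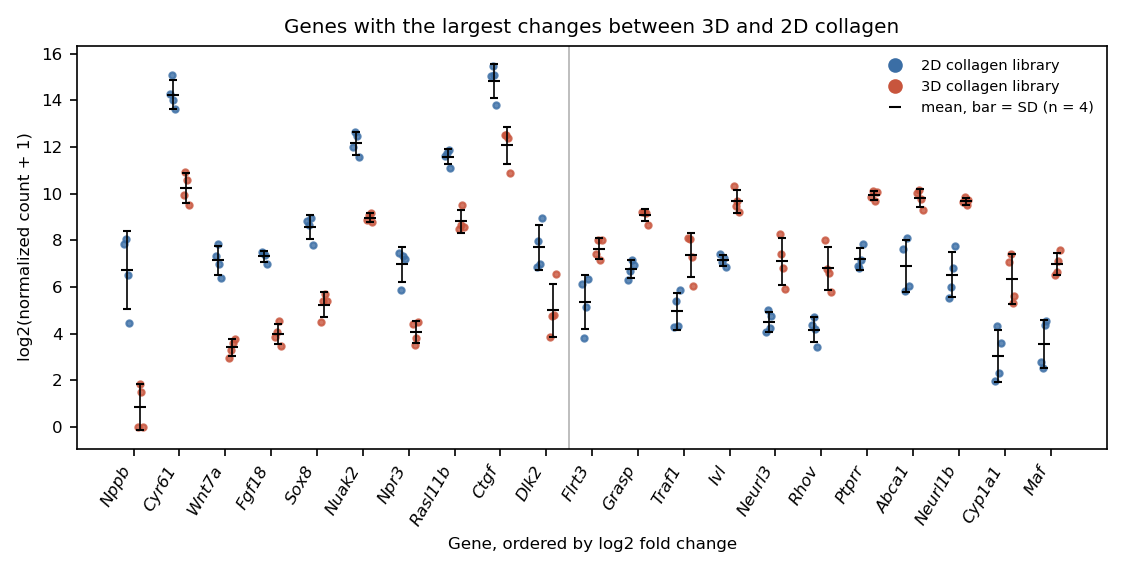
Values per library, as log2(normalized count + 1), of 10 of the 12 genes with the largest decrease (left of the vertical line) and 11 of the 12 with the largest increase on 3D collagen, with blue points for 2D and red points for 3D libraries and black bars for the mean and SD (n = 4). The rule that chose these genes required that the groups not overlap, so the lack of overlap in the 21 genes drawn follows from the choice. The lowest 2D value of Nppb, 20.8 normalized counts, is in 2D replicate 4.

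Genes of cholesterol synthesis fell on 3D collagen. Of 24 tested members, 16 passed the threshold, 19 did so adjusted over the list alone, and all 24 had log2 fold changes below 0, with a median of −1.17. Hsd17b7 (chromosome 1, 169949535 to 169969241), which reduces a sterol intermediate, fell from 709 ± 127 to 144 ± 18.4 normalized counts, a log2 fold change of −2.28 (SE 0.20, limma adjusted p = 0.00127). The log2 fold changes of the sterol carrier Stard4 and of lanosterol synthase (Lss) were −1.69 and −1.21. The list was called by camera (adjusted p = 2.72e-17), with adjusted p = 0.175 with an estimated correlation, and fry gave an adjusted p of 0.000749. After the GC trends were removed 17 members were lower. In 7 of the 35 splits of the libraries into 4 and 4, the real one included, some list had a camera p as small, and for this list by itself it was 1, the real one.

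Targets of SRF and its cofactors MRTF, which tie transcription to actin, fell in 8 of 26 tested members (12 adjusted over the list alone). The median log2 fold change was −0.83 (camera adjusted p = 1.75e-07, adjusted p = 0.513 with an estimated correlation). In 5 of the 35 splits, the real one included, this list had a camera p as small, and the smallest in another split was 1.32e-14. The groups overlapped in the list's median deviation from the mean of all libraries (log2), at −0.16 in 2D replicate 4 and −0.09 in 3D replicate 2. By the same measure they overlapped for the NRF2, NF-kappaB, interferon, smooth muscle, Wnt and non-collagen matrix lists. Srf itself (chromosome 17, 46548329 to 46556175) fell from 3792 ± 1135 to 1026 ± 163 normalized counts, a log2 fold change of −1.86 (SE 0.21, limma adjusted p = 0.00311), and 2D replicate 2 stood apart at 5494. The actin crosslinker filamin A (Flna) fell from 202790 ± 36383 to 84102 ± 17987, while Fhl2 and Tuft1 had log2 fold changes of −1.18 and −1.65. Tuft1 was lowest in 3D replicate 4 (322). Focal adhesion components fell in 7 of 30 members (16 adjusted over the list alone; median −0.71; camera adjusted p = 3.14e-06; adjusted p = 0.513 with an estimated correlation), among them the adaptor Bcar1 (log2 fold change −1.36), talin 1 (Tln1, −1.30) and tensin 1 (Tns1, −1.49). In the smooth muscle list, which holds contractile genes, 2 of 6 tested members fell (2 adjusted over the list alone; median −1.11; camera adjusted p = 0.00127; adjusted p = 0.513 with an estimated correlation). They were smoothelin (Smtn, 24860 ± 4781 to 5150 ± 1185) and leiomodin 1 (Lmod1, 44.5 ± 21.6 to 4.61 ± 2.37), and antisense gene models overlap 17.2% of the exonic bases of Smtn.

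After the GC trends were removed 9 SRF and MRTF targets, 11 focal adhesion components and 2 smooth muscle genes were lower. The SRF and MRTF count fell to 4 without any one of 2D replicates 1 and 3 and 3D replicates 1, 2 and 4, to 5 without 2D replicate 2 and to 3 without 3D replicate 3. The focal adhesion count fell to 4, 2, 3 and 1 without 2D replicate 3 and 3D replicates 1, 2 and 3. In limma the calls of Tln1 and Tns1 were lost without 3D replicate 1 (adjusted p = 0.0504 and 0.0581) or 3 (0.0830 and 0.0842), that of Tln1 without 2D replicate 3 (0.0534), that of Tns1 without 3D replicate 2 (0.0688) and that of Flna without 3D replicate 3 (0.0544).

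YAP and TAZ targets, which respond to cell shape and stiffness, fell in 10 of 25 tested members and rose in 1 (11 and 2 adjusted over the list alone), with a median log2 fold change of −0.60. Besides Cyr61, Ctgf and Nuak2, Wwc1 fell from 5507 ± 1285 to 2029 ± 194 normalized counts and Ajuba (Jub in the deposited values) from 6418 ± 1305 to 2657 ± 387. Asap1, named after its value was seen, rose with a log2 fold change of 1.07. The list was called by camera (adjusted p = 0.000659; adjusted p = 0.513 with an estimated correlation). After the GC trends were removed 10 members were lower and 2 higher. The lower count fell to 6 without 3D replicate 1 or 3, and the higher count to 0 without 3D replicate 2 or 3.

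Targets of NRF2, a regulator of the antioxidant response, rose in 5 of 28 tested members (11 adjusted over the list alone), with a median log2 fold change of 0.62 (camera adjusted p = 5.10e-06; adjusted p = 0.513 with an estimated correlation). The groups overlapped in the list's median deviation from the mean of all libraries (log2), at 0.03 in 2D replicate 2 and −0.05 in 3D replicate 4. The quinone reductase Nqo1 rose from 58.6 ± 20.9 to 201 ± 70.4 normalized counts. Catalase (Cat) rose from 1960 ± 762 to 4341 ± 542 and the glutathione transferase Gsta4 from 731 ± 274 to 1777 ± 477. The cystine transporter Slc7a11, named after its value was seen, had a log2 fold change of 1.95. The glutathione synthesis gene Gclm had a log2 fold change of 1.05 (limma adjusted p = 0.0340), which did not pass after the GC trends were removed (limma adjusted p = 0.241, range over the alternatives 0.00152 to 0.897), and other gene models overlap 8.58% of its exonic bases. FOXO targets rose in 5 of 18 members (6 adjusted over the list alone; median 0.79; camera adjusted p = 0.000126; adjusted p = 0.513 with an estimated correlation). The repressor Bcl6, the ubiquitin ligase Fbxo32, the pyruvate dehydrogenase kinase Pdk4 and the cyclin Ccng2 had log2 fold changes of 1.79, 2.23, 0.95 and 1.13, with Ccng2 highest in 3D replicate 1 (1068), and Sesn3, named after its value was seen, had 0.85. The NRF2 count was 1 without 2D replicate 1 or 3, 0 without 3D replicate 1 or 2, 2 without 3D replicate 3 or 4 and 1 without both libraries numbered 4, and it was 10 with library size as the only scaling. The FOXO count was 1 without 3D replicate 1 or 2, 2 without 3D replicate 3 and 3 without both libraries numbered 4. The calls of Nqo1 and Gclm were lost without 2D replicate 1 or 3 or 3D replicate 1, 2 or 4, that of Cat without 2D replicate 4 or any 3D replicate and that of Gsta4 without 2D replicate 1 or 3 or any 3D replicate. Limma adjusted p was then from 0.0509 to 0.115. Without 3D replicate 1, Pdk4, Fbxo32 and Ccng2 reached limma adjusted p of 0.0708, 0.0633 and 0.0733, without 3D replicate 2 they reached 0.0750, 0.0716 and 0.0697, and without 3D replicate 3 Fbxo32 and Ccng2 reached 0.0794 and 0.0758.

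NF-kappaB targets and chemokines rose in 3 of 23 tested members and fell in 1 (7 and 1 adjusted over the list alone), with a median log2 fold change of 0.82 (camera adjusted p = 0.000830; adjusted p = 0.532 with an estimated correlation). The neutrophil chemokines Cxcl5 and Cxcl2 rose from 8.05 ± 4.64 to 55.9 ± 22.2 and from 7.13 ± 3.70 to 32.5 ± 16.1 normalized counts, as did Traf1. Tnfaip3, a feedback inhibitor of NF-kappaB, fell from 1141 ± 148 to 576 ± 132. Interferon-stimulated genes rose in 2 of 17 members (4 adjusted over the list alone; median 0.66; camera adjusted p = 0.0143; adjusted p = 0.532 with an estimated correlation), namely Oasl2 (log2 fold change 1.73) and Irf7 (1.09). Fry called neither list, with an adjusted p of 0.115 for NF-kappaB targets and 0.110 for interferon-stimulated genes. A camera p as small occurred for them in 9 and 7 of the 35 splits, the real one included. Without 3D replicate 1, 2 or 3 the count of higher members was 0 in both lists. It was 1 in the NF-kappaB list without 2D replicate 1 or 3 and 1 in the interferon list without 2D replicate 4 or 3D replicate 4, while the NF-kappaB list had 6 higher members without 3D replicate 4 and 9 without both libraries numbered 4. The call of Tnfaip3 was lost without 3D replicate 1 or 3 (limma adjusted p = 0.0585 and 0.0845). Those of Cxcl5 and Oasl2 were lost without 3D replicate 1, 2 or 3 (limma adjusted p from 0.0538 to 0.0830). That of Cxcl2 was lost without any one library except 2D replicate 4, and that of Irf7 without any except 2D replicates 2 and 3, at limma adjusted p of up to 0.123 and 0.121.

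Wnt ligands and receptors fell in 5 of 16 tested members (5 adjusted over the list alone), with a median log2 fold change of −0.38 (camera adjusted p = 0.00242; adjusted p = 0.513 with an estimated correlation). Wnt7b fell from 16910 ± 4444 to 4917 ± 541 normalized counts, and Wnt7a, Wnt9a and the receptor Fzd2 had log2 fold changes of −3.73, −1.67 and −1.39. Wnt4 had a log2 fold change of −0.93 (limma adjusted p = 0.0360), and it did not pass after the GC trends were removed (limma adjusted p = 0.0591, range over the alternatives 0.00403 to 1.00) or without any one library except 3D replicate 4 (limma adjusted p from 0.0507 to 0.114). Without 3D replicate 1 the Wnt count was 3 and Wnt9a reached a limma adjusted p of 0.0516.

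Beta-catenin target genes rose in 4 of 13 members and fell in 1 (6 and 1 adjusted over the list alone; median 0.82; camera adjusted p = 0.0158; adjusted p = 0.513 with an estimated correlation). Sox9 rose from 807 ± 273 to 2257 ± 452 normalized counts. The stem cell receptor Lgr5 rose from 105 ± 35.0 to 348 ± 98.8 and the hyaluronan receptor Cd44 from 2955 ± 298 to 5311 ± 1242. Myc fell from 801 ± 182 to 371 ± 51.3, with 3D replicate 2 highest at 448. Tcf7, named after its value was seen, had a log2 fold change of 1.16. The call of the list was lost without 2D replicate 1 (camera adjusted p = 0.0822), and that of Cd44 after the GC trends were removed (limma adjusted p = 0.135, range over the alternatives 0.00265 to 1.00) and without 2D replicate 2, 3 or 4 or 3D replicate 1, 2 or 3 (limma adjusted p from 0.0623 to 0.117). Without 2D replicate 2 or 4 or 3D replicate 4, 2 of the targets were higher, without 3D replicate 1 it was 1, without 3D replicate 2 or 3 it was 0, and Myc was no longer called without 3D replicate 1 or 3 (limma adjusted p = 0.0622 and 0.0768). Sox9 was not called without 3D replicate 1, 2 or 3 (limma adjusted p from 0.0630 to 0.0688), and Lgr5 without 3D replicate 2, 3 or 4 (0.0791, 0.0813 and 0.0507).

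Some matrix genes fell. In matrix crosslinking and collagen processing 2 of 17 tested members fell (5 adjusted over the list alone; median −0.55; camera adjusted p = 0.00127; adjusted p = 0.513 with an estimated correlation), the lysyl oxidase Loxl4 from 1380 ± 101 to 650.2 ± 161 normalized counts and the procollagen protease Bmp1 from 2886 ± 592 to 1627 ± 147. Among non-collagen matrix components 2 of 26 fell (6 lower and 1 higher adjusted over the list alone; median −0.43; camera adjusted p = 0.0471; adjusted p = 0.782 with an estimated correlation). They were thrombospondin 1 (Thbs1, 6242 ± 2921 to 1160 ± 372) and fibronectin (Fn1, 146225 ± 27832 to 70222 ± 11534). This list was not called after the GC trends were removed (camera adjusted p = 0.112, and 0.0726 with 2D replicate 2 left out as well), nor without 2D replicate 1, 2 or 3 or 3D replicate 4 (camera adjusted p = 0.102, 0.0550, 0.233 and 0.144). It was also not called with no filter beyond 1 read or with a minimum of 1 CPM in 4 libraries (camera adjusted p = 0.0940 and 0.0658), and fry gave an adjusted p of 0.280. The crosslinking count was 1 without 2D replicate 1 or 3 or any 3D replicate, since Bmp1 was then not called (limma adjusted p from 0.0628 to 0.0940). The non-collagen count was 1 without 2D replicate 3 or 3D replicate 2, where Fn1 reached limma adjusted p of 0.0525 and 0.0607, and 0 without 3D replicate 3, where Thbs1 and Fn1 reached 0.0543 and 0.0844.

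The list of matrix proteases and inhibitors was not called, with 2 of 28 members higher and 3 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.917). Adamts1 rose from 2221 ± 223 to 5732 ± 930 normalized counts and Adamts4 from 57.3 ± 21.5 to 256 ± 76.0, while Adam8 fell from 1334 ± 180 to 660 ± 110 and Mmp15, named after its value was seen, had a log2 fold change of −1.47. Without 3D replicate 1, 2 or 3 the higher count was 1, since Adamts4 was then not called (limma adjusted p = 0.0509, 0.0549 and 0.0577). In collagen genes limma called 0 of 18 members (0 adjusted over the list alone), where 1 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 1. Col18a1 stood at 40765 ± 10464 on 2D and 24541 ± 2615 on 3D collagen (limma adjusted p = 0.0711, 0.0337 after the GC trends were removed, range over the alternatives 0.0148 to 1.00), and Col6a1 at 4590 ± 1617 and 3392 ± 2203 (limma adjusted p = 0.425).

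Of 18 integrins and collagen receptors only Cd44 passed (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.902), and without 2D replicate 2, 3 or 4 or 3D replicate 1, 2 or 3 the count was 0. In limma the log2 fold changes were 0.59 for Itga1 (adjusted p = 0.408), −0.09 for Itga2 (0.934), −0.95 for Itga3 (0.119), −0.30 for Itgb1 (0.569), −0.04 for Ddr1 (0.940) and −0.15 for Ddr2 (0.749), and those of Itga2, Ddr1 and Ddr2 changed sign under some scalings. Itgb1 was highest in 2D replicate 1 (23515 normalized counts) and Itga1 lowest among 3D libraries in replicate 4 (57.6). The membrane-bound metalloproteinase Mmp14 stood at 2572 ± 691 on 2D and 3866 ± 727 on 3D collagen (limma adjusted p = 0.168), with 2D replicate 4 apart at 1547. Col1a1 stood at 72.5 ± 26.9 and 41.6 ± 11.9 (limma adjusted p = 0.253), with 3D replicate 2 apart at 59.4. Col1a2 and Col3a1 were too low to test, Col1a2 at 5.46 ± 5.62 and 1.17 ± 1.09 and Col3a1 at 5.90 ± 2.35 and 6.93 ± 4.18.

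**Figure D2:**
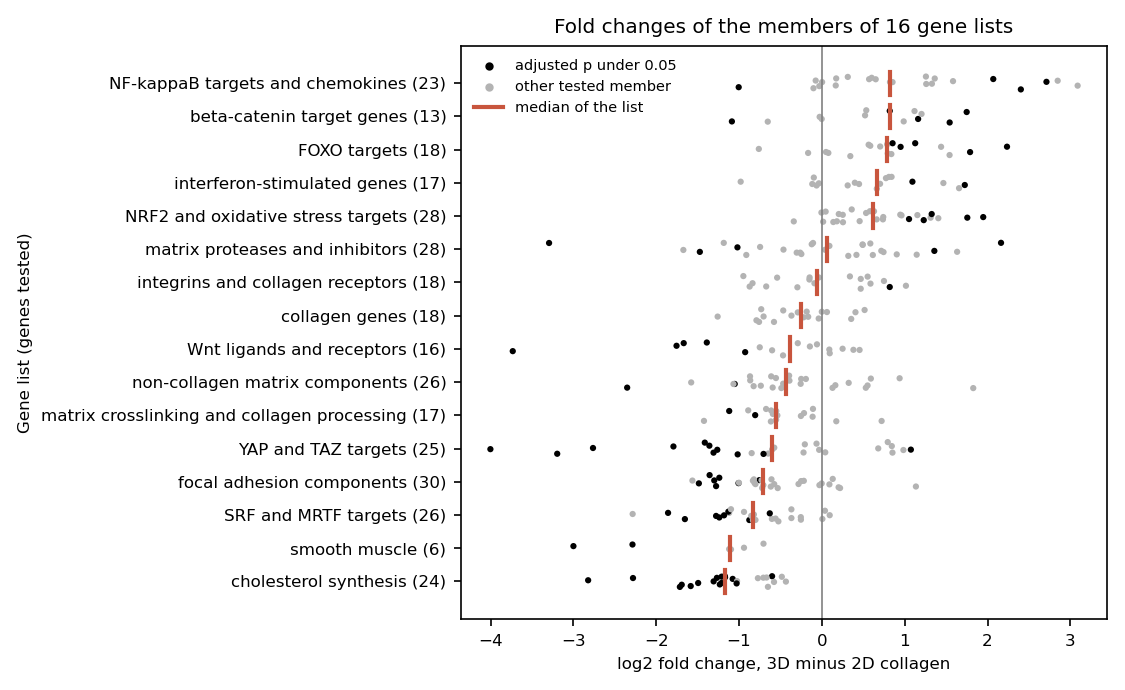
Log2 fold changes (3D minus 2D collagen) of the tested members of the 13 called gene lists and of the integrin, collagen and matrix protease lists, with black points for an adjusted p under 0.05, grey points for other members and red bars for the median. Medians run from 0.82 for NF-kappaB and beta-catenin targets to −1.17 for cholesterol synthesis, where every member lies below 0.

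The oviductal transcription factor Pax8, the intermediate filament vimentin (Vim) and E-cadherin (Cdh1) did not pass the test. Pax8 stood at 10271 ± 1404 on 2D and 9494 ± 1518 normalized counts on 3D collagen (limma adjusted p = 0.723). Vim stood at 72850 ± 9813 and 87320 ± 11323 (limma adjusted p = 0.382) and Cdh1 at 64.0 ± 32.1 and 61.8 ± 35.5 (limma adjusted p = 0.956). The differences of Pax8 and Cdh1 changed sign under some scalings. Keratin 8 (Krt8) fell from 34270 ± 5557 to 20133 ± 3079 (limma adjusted p = 0.0397), a call lost without any one library except 2D replicate 4 (limma adjusted p from 0.0628 to 0.134). Members of the secretory list summed to 8713 ± 442 CPM on 2D and 7592 ± 571 on 3D collagen, and of 11 tested only Lgr5 was called. Fibroblast markers summed to 17.4 ± 6.26 and 21.5 ± 4.78 CPM, endothelial markers to 51.5 ± 19.0 and 54.6 ± 16.3, and leukocyte markers to 152 ± 25.5 and 178 ± 56.4. Ciliated cell markers summed to 503 ± 168 and 290 ± 83.5, mesothelial markers to 2167 ± 262 and 1861 ± 390, and smooth muscle markers to 2793 ± 867 and 1088 ± 350. These sums were not tested.

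In the lists that camera did not call, the members named here were chosen after their values were seen. Higher were the growth factor receptor Pdgfra, which the fibroblast and mesenchymal lists share, and the mesenchymal Twist2, with log2 fold changes of 1.73 and 1.69. Pdgfra was low, at 4.65 ± 2.40 normalized counts on 2D and 16.6 ± 1.88 on 3D collagen. The higher count of either list was 0 without 2D replicate 1 or 3 or any 3D replicate. Lower were 1 of 16 mesenchymal genes (Fn1) and 3 of 24 epithelial keratins and junction genes (Krt8, Esrp2 and Pkp2). Of 30 targets of the amino acid response Cebpb, Ddit3, Ddit4 and Slc7a11 were higher and Slc7a1 lower, of 25 p53 targets Bbc3, Ddit4 and Perp were higher, and of 49 nuclear-encoded genes of oxidative phosphorylation Atp5j, Cox6c and Ndufa4 were higher. Of 26 hypoxia targets Ddit4 and Mxi1 were higher and Adm lower, of 24 immediate early genes Klf4 was higher and Myc and Srf lower, and of 29 PI3K and AKT pathway genes Sesn3 was higher and Pik3cb lower. Of 38 genes of ribosome biogenesis Bysl, Polr1b and Rrp12 were lower, and of 26 endoplasmic reticulum chaperones Hyou1 was. Leaving out 3D replicate 1, 2 or 3 brought several of these counts to 0. These were the higher counts of the amino acid response, oxidative phosphorylation, hypoxia, immediate early and PI3K and AKT lists. The lower counts of the ribosome biogenesis and epithelial lists went to 0 as well. TGF-beta targets had 5 of 21 members lower (5 higher and 6 lower adjusted over the list alone, and 3 higher and 6 lower after the GC trends were removed), with a median of 0.06 and a mean of −0.25, opposite in sign. Limma called 0 of 207 members in 11 lists, where 20 had an unadjusted p under 0.05, edgeR called 0 and DESeq2 called 9: DNA replication, mitosis, replication-dependent histones, glycolysis, heat shock proteins, cytosolic ribosomal proteins, collagen genes and the mesothelial, endothelial, ciliated and leukocyte markers. As a list, DNA replication was not called by camera (adjusted p = 0.170), but it was called lower in 5 of 18 alternatives. Among these were the replicate block, leaving out both libraries numbered 4 and leaving out 3D replicate 4. Cytosolic ribosomal proteins were called lower in 4 of 18. The mitochondrially encoded list had 0 tested members. Over the 30 lists not called, 22 distinct genes were higher and 30 lower. With library size as the only scaling 37 were higher and 25 lower in limma and 35 and 25 in edgeR, with upper-quartile scaling 31 and 29 in edgeR, and DESeq2 gave 47 and 56. The counts were 11 and 25 without 2D replicate 1, 11 and 16 without 2D replicate 3, 11 and 26 without 2D replicate 4, 4 and 13 without 3D replicate 1, 2 and 12 without 3D replicate 2, and 2 and 9 without 3D replicate 3. Of the 13 called lists, 0 held with an estimated correlation in camera, where 1 had an unadjusted p under 0.05. By fry 10 of them had an adjusted p under 0.05, and the NF-kappaB, interferon and non-collagen matrix lists did not. At least 13 lists were called by camera in 9 of the 35 splits of the libraries into 4 and 4. Taken list by list, a camera p as small occurred in 3 splits for focal adhesion and for YAP and TAZ targets, the real split included. It occurred in 4 for the FOXO, crosslinking, Wnt and beta-catenin lists and in 5 for the SRF and MRTF, NRF2 and smooth muscle lists. For interferon-stimulated genes it was 7, for NF-kappaB targets 9 and for non-collagen matrix components 12.

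The libraries differed within groups in GC trend and in proliferation genes. The correlation across genes between a library's deviation from the mean and transcript GC content (Spearman's rho; genes are not independent replicates) was 0.69 in 2D replicate 2, −0.44 in 2D replicate 1 and −0.47 in 3D replicate 4. Log2 fold changes fell with GC content across genes (rho = −0.38), and rho was −0.0816 without 2D replicate 2. After the GC trends were removed 506 genes were higher and 625 lower, and 616 of the 675 called genes with a GC value kept their call. The 76 tested members of the DNA replication and mitosis lists had median deviations from their group means of 1.39 in 2D replicate 4 and 1.46 in 3D replicate 4 (log2). The proliferation marker Mki67 reached 533 normalized counts in 2D replicate 4 and 2299 in 3D replicate 4. Without both of these libraries 171 genes were higher and 276 lower.

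**Figure D3:**
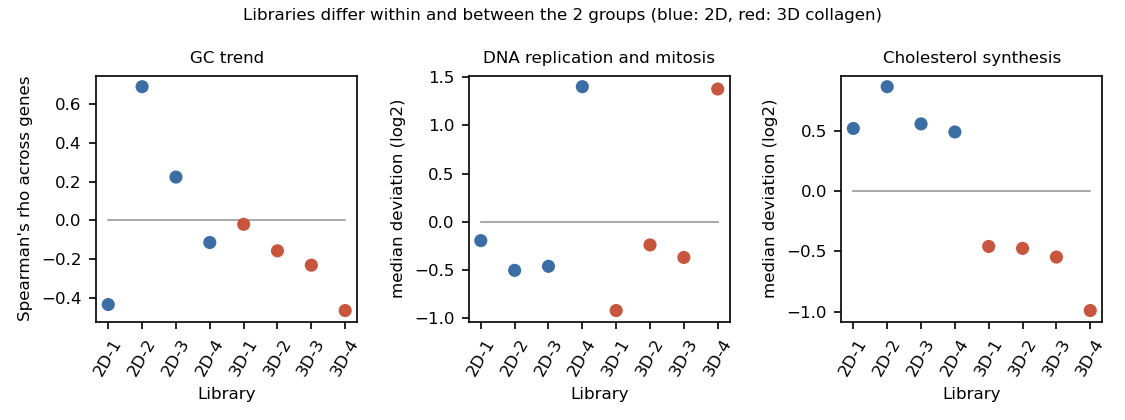
For each library, the Spearman correlation across genes of its deviation with transcript GC content (left) and the median deviation from the mean of all libraries (log2) of DNA replication and mitosis genes (middle) and of cholesterol synthesis genes (right), in blue for 2D and red for 3D collagen. The GC correlation is highest in 2D replicate 2 (0.69), both libraries numbered 4 stand apart in the middle panel at 1.40 and 1.38, and the cholesterol medians of all 2D libraries lie above those of all 3D libraries.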

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

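The GC correction was chosen after the data were seen, and the test of dividing cells only after its result was seen. Of 174 groups of 4 values (named genes and library measures), 12 had 1 library set apart from the other 3 by a gap that took more of the group's range than Dixon's 95% critical value, where chance sets apart about 1 in 20. Of the 12, 6 were in 2D replicate 4 or 3D replicate 4.

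On 2D collagen, Srf was highest in replicate 2 at 5494 normalized counts, with a gap of 0.946 of the range. Itgb1 was highest in replicate 1 at 23515 (0.877), and Mmp14 lowest in replicate 4 at 1547 (0.840). On 3D collagen, replicate 4 was lowest for Ctgf at 1884 (0.881), Grasp at 409 (0.871), Tuft1 at 322 (0.940) and Itga1 at 57.6 (0.832), and highest for Dlk2 at 92.4 (0.8291). Rasl11b was highest in 3D replicate 3 at 741 (0.862), Ccng2 in 3D replicate 1 at 1068 (0.889), and Myc and Col1a1 in 3D replicate 2 at 448 (0.883) and 59.4 (0.896).

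2D replicate 4 and 3D replicate 4 deviated together from their groups, with a correlation of 0.81 across genes. GC trends that differ between libraries are argued against, since the correlation stayed at 0.78 after they were removed. A higher share of dividing cells in both is a candidate explanation. The lower of their median deviations over 76 DNA replication and mitosis genes was 1.39, although the correlation was 0.80 outside these genes as well. A shared culture or day stays open, since the labels give no batch.

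Log2 fold changes fell with transcript GC content across genes (rho −0.38). A candidate explanation is 2D replicate 2 alone, since rho was −0.0816 without it. GC trends are argued against as the whole cause of the calls, because 91.3% of the called genes with a GC value stayed called in the same direction after removal. They are argued against as the whole cause of the lower SRF and MRTF, focal adhesion, YAP and TAZ and cholesterol synthesis lists too. Their 100 members together had a median log2 fold change of −0.74 before and −0.74 after. Each list's own median moved toward 0. It went from −0.71 to −0.52 for focal adhesion, −0.83 to −0.77 for SRF and MRTF, −0.60 to −0.52 for YAP and TAZ and −1.17 to −1.08 for cholesterol synthesis. The substrate itself stays open as a biological explanation of these lower lists, as a hypothesis found on the same data.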

How the results depend on the processing

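The GC correction, leaving out both libraries numbered 4, the limma fits with TMM or library size, the pseudocounts and edgeR with the block were chosen after the data were seen, and edgeR with TMM, planned for raw counts, was then run on the recovered reads instead. Of the 67 named genes called, 0 changed direction under any limma, edgeR or DESeq2 alternative. Cyr61 passed in all 25 alternatives, whereas Wnt4 lost its call in 14, Dlk2 in 13 and Krt8 in 11. Not called otherwise, Itga3 passed in 1 (DESeq2), Col18a1 in 2 (DESeq2, GC correction) and Mmp14 in 2 (replicate block). Higher and lower genes, against 275 and 401, numbered 498 and 318 with library size in limma, 415 and 380 with edgeR and upper-quartile factors, 481 and 324 with edgeR and library size, 692 and 851 with DESeq2, and 9 and 37 against a 1.5-fold change. The GC correction gave 506 and 625, with 2D replicate 2 left out as well 419 and 497, and leaving out both libraries numbered 4 gave 171 and 276. DESeq2 shared 676 of the called genes, and edgeR with TMM 630. Without 1 library, higher genes ranged from 44 to 267 and lower genes from 104 to 370; for each fewer samples were tested, and otherwise the causes were not tested. The replicate numbers were not taken to pair the libraries, since nothing in the labels says that they mark a shared day or batch. The correlations of same-numbered deviations were −0.17, 0.37, 0.25 and 0.81, and those of other pairs ran from −0.62 to 0.45. Not every library correlated best with its own number. These values do not settle whether the numbers pair the libraries. A day shared by some of them stays open. With the replicate block 663 and 742 genes were called, and in edgeR 718 and 642. Lists called numbered 13, and 0 with camera's estimated correlation; leaving out 1 library gave 12 to 17. At this depth 11820 of 23337 gene symbols passed the minimum for testing, and Col1a2 and Col3a1 did not.

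In limma, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, changed as many genes (676 against at most 0). At an unadjusted p under 0.05 there were 2865 genes against at most 1708. Likewise it was 1 in each direction (275 higher and 401 lower, against at most 0). This argues against chance for these counts but does not exclude it, since 1 of 35 is the smallest share these splits can give. The splits also treat the libraries as exchangeable, while a day shared by some of them stays open. Chance cannot be excluded for the number of lists, since 9 of the 35 splits called at least 13 lists and the highest other number was 21.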

Other observations

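The LXR, aryl hydrocarbon receptor, cornified-envelope, liver and intestine lists, the test of cornified-envelope genes, the comparison of the smallest camera p across the splits and the genes of the next paragraph were chosen after the values were seen.

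Some lists that camera did not call held called members. Of 10 EGF family ligands and receptors the ligand Hbegf and the receptor Egfr fell, with −2.57 and −1.21, and the count stayed at 2 whichever library was left out. Of 28 apoptosis regulators (camera adjusted p = 0.255, median 0.10) Bik, Bbc3 and Bid rose, with 3.19, 1.44 and 0.72, and 1 was called without 3D replicate 2 or 3. Bik was low, at 1.72 ± 1.27 normalized counts on 2D and 24.3 ± 14.1 on 3D collagen. The related Bmf, Bcl2l11, Pmaip1 and Bad did not pass, with 1.29, 0.67, 0.28 and −0.33. Of 20 ERK feedback genes (camera adjusted p = 0.609) Dusp4 and Dusp7 rose, with 1.69 and 1.15, and Dusp6 and Dusp5 did not pass, with 1.58 and −1.33, while Epha2, Epha4 and Myc fell, with −1.89, −1.44 and −1.09. Without 3D replicate 1, 2 or 3 the higher count of this list was 0 and the lower count 1, 2 and 1, and without 2D replicate 1, 3 or 4 the higher count was 1. Of 21 TGF-beta targets (5 higher and 6 lower adjusted over the list alone) those that fell included Pmepa1, Smad6 and Ltbp3, with −1.31, −1.21 and −0.93. The lower count of 5 was 3 without 2D replicate 1 or 3 or 3D replicate 2 and 2 without 3D replicate 1 or 3.

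Cholesterol synthesis had the smallest camera p of the 41 lists (6.63e-19). In 7 of the 35 splits, the real one included, some list had a camera p as small, and the smallest in another split was 8.38e-25, for cytosolic ribosomal proteins, so chance cannot be excluded for the smallest p among the lists. For this list by itself 1 of the 35 splits, the real one, had a camera p as small (3.21e-12 for the next) and 1 a median as far from 0 (1.17 against 0.74), which does not allow for its having been picked from 41 lists. More sterol in the cells could lower these genes through SREBP2, and would raise LXR targets. Abca1 rose. Apoe had a log2 fold change of 1.37 (limma adjusted p = 0.441), but within each group its order across libraries was that of the liver transcripts given last. The 7 other LXR targets tested had a median of −0.0264 with 3 above 0, of which Arl4c was called at 1.00. Against other genes camera did not set them apart at a p under 0.05. The outcome written down before this test as going against the hypothesis was a median below 0, and the median lay there. It lay below 0 by less than the spread of the members, a margin that was not part of that criterion. With this margin the hypothesis stays open.

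Cyp1a1 is a known target of the aryl hydrocarbon receptor, whose activation could raise it. The 5 other targets tested had a median log2 fold change of 0.58. Called higher were Nqo1, which the NRF2 list also holds, and Nfe2l2, the gene of NRF2 itself. Cyp1b1, Tiparp and Ugt1a6a were not called, with −0.57, 0.21 and 0.58. Within groups Cyp1a1 was highest in libraries that also had more intestine transcripts, given last. Between groups it did not follow them. In 3D replicates 3 and 4 the intestine sums (0.472 and 0.597 CPM) lay under those of every 2D library. Cyp1a1 stood there at 38.2 and 47.6 normalized counts, above the highest 2D value of 19.1. Camera did not set the 5 other targets apart from other genes, so activation of the receptor was not decided. The rise of Ivl may be part of an induction of cornified-envelope genes. The 9 others tested had a median of 0.44, and 7 lay above 0. Camera did not set them apart either, so this too was not decided.

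Transcripts of 8 liver genes summed to 7.64, 31.7, 13.4 and 2.93 CPM in 2D replicates 1 to 4 and to 34.2, 9.84, 3.56 and 0.760 in 3D replicates 1 to 4. Transcripts of 8 intestine genes summed to 1.42, 27.1, 3.83 and 4.08 and to 15.9, 11.2, 0.472 and 0.597. The liver gene Alb stood at 106 ± 138 and 76.5 ± 138 normalized counts and the intestine gene Reg3b at 67.0 ± 115 and 33.5 ± 44.3 on 2D and 3D collagen. The source of these transcripts was not worked out. Apoe stood at 322, 989, 576 and 65.0 normalized counts in 2D replicates 1 to 4 and at 2514, 1427, 1040 and 144 in 3D replicates 1 to 4. Cyp1a1 was highest in 2D replicate 2 (19.1) among 2D libraries and in 3D replicates 1 and 2 (132 and 172) among 3D libraries. It stood at 38.2 and 47.6 in 3D replicates 3 and 4, which had the lowest intestine sums, and 3D replicate 4 also had the lowest liver sum.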
